A study of Mus musculus with 12 samples.

How the data were processed

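RNA of GFP-sorted AML246 bone marrow cells was measured by bulk RNA sequencing in 12 libraries, 3 for untreated cells and 3 each for 2, 4 and 6 days of Dox. Per the labels, RNA was extracted with a column kit and standard Illumina libraries were made. The deposited files hold raw read counts for 27179 Entrez genes with a gene length for each, which the authors made before deposition with no normalisation applied. The processing notes name CASAVA 1.8.2, featureCounts, edgeR 3.8.2, limma 3.22.0 and the mm10 genome without assigning them steps, and the aligner and the strand setting are not given in the sources used here. The counts were whole numbers with a different total in each library, and no library duplicated another. Gene identifiers were given symbols and positions from the RefSeq annotation of GRCm38 (25275 identifiers) and from GENCODE (18), and 1886 stayed unnamed and held 0.487% to 1.06% of the counts of a library.

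The counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes with enough counts by filterByExpr were kept (12057), TMM factors were computed, and all 12 libraries were fitted together with the group as the only term (glmQLFit with robust dispersion, 8 residual degrees of freedom). The biological coefficient of variation was 14.3%. The TMM factors were 1.02 to 1.15 in the untreated, day 2 and day 4 libraries and 0.737, 0.847 and 0.749 in the day 6 libraries. Each day was compared with untreated, day 4 with day 2 and day 6 with day 4, by the quasi-likelihood test, two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. A test of the 3 day coefficients together covered any change over the 4 groups. A transient gene was called at day 2 and called from day 2 to day 6 in the opposite direction. Levels of Spi1 and Trp53 were also compared by exact two-sided permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries can give. Principal components were computed on log2 CPM of the tested genes.

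Gene lists, the genes to be named and the alternatives were fixed before the data were examined, except where the text says otherwise. The 37 lists held 793 genes of myeloid lineage, receptors, cell cycle, metabolism, stress and markers of other marrow cells, of which 650 were tested. Some lists share genes, so their calls are not independent. Of the PU.1-regulated list 26 of 31 genes stand in another list, of mature neutrophil genes 13 of 35 and of monocyte and macrophage genes 12 of 32. The 33 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists and the 3 days, and again with an estimated correlation and with fry, whose p tests whether a list moves on balance one way without comparing it with other genes. The genes named are Spi1 and Trp53, a fixed set of maturation and cell cycle genes, and the 8 genes with the largest rise and the 8 with the largest fall at each day among called genes of at least 10 CPM whose libraries did not overlap, predicted gene models left out. The rule also takes 3 and 3 genes for each step between days, up to 4 called genes of a list in its main direction and 2 in the other, and up to 5 transient genes of each direction. It gave 284 genes, of which 146 are named here. All genes of the fixed set, the largest changes and the transient changes are among them, and which of the list members to name was decided for length after the values were seen.

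The procedure was tested on simulated data with 11859 genes tested. It recovered 28% to 32% of planted 1.5-fold changes, 68% to 78% of 2-fold, 93.75% of 4-fold and 95.9% to 98.0% of 8-fold changes, and called 0 genes in data without planted changes. Beside the planted changes, 3 to 7 of 11662 unchanged genes were called. Changes were planted in 200 genes, as many up as down, with counts drawn from dispersions fitted to the data. In the data 42.4% of genes were called at day 4 and 67.9% at day 6. The simulation did not test the scaling under such broad change, so its shares may not hold at those days. Overlaps between days were set against 20 simulations without effects, taking as many genes by p as were called. The alternatives were DESeq2, limma voom, 3 other scalings (RLE, upper-quartile and library totals), no filter and a stricter filter of 5 CPM in 3 libraries, a 1.5-fold threshold with glmTreat, fits of only the groups compared, the replicate number as a block, and each library left out in turn. The main fit had no block because the sample titles call the replicates technical, so the block stands only among the alternatives. No general pairing by replicate number was seen. The correlation of residuals between libraries of the same number in different groups averaged 0.006 over 18 pairs (-0.17 to 0.29). Of 12 libraries 4 were closest to their own number. A pairing of some samples is not excluded.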

Results

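The series measured RNA in AML246 cells, a cytogenetically normal mouse acute myeloid leukemia that lacks p53 and carries a doxycycline-responsive hairpin against PU.1 with a linked GFP marker. Doxycycline (Dox) switched the hairpin off in leukemic mice, and PU.1, the myeloid transcription factor encoded by Spi1, was restored over days. Leukemic cells were sorted from bone marrow by GFP before Dox and after 2, 4 and 6 days. The 12 libraries formed 4 groups of 3, named untreated, Dox day 2, Dox day 4 and Dox day 6. The sort gate moved from high to low GFP with the days, so the gate and the time on Dox cannot be separated. All libraries came from AML246 cells, so an effect of Dox itself cannot be separated from hairpin shut-off. The sample titles call the replicates technical, while the series design speaks of triplicate mice. The p-values therefore measure the spread between these samples, which may be technical. Between replicates of a group the variance of counts was 2.53 to 41.0 times that of counting error. These values argue against repeated sequencing of 1 library, while repeated preparations, sorts or mice stay open. Total counts of replicates 1, 2 and 3 were 6157782, 6593582 and 6337478 in untreated cells, 5805520, 4918920 and 6705112 at day 2, 6449662, 6728656 and 6664498 at day 4 and 6372953, 7356166 and 6844235 at day 6. At these depths 3 counts corresponded to 0.393 to 0.640 CPM (counts scaled to library size). Intervals and floors of this kind cover counting error only. Values below are TMM-normalised CPM as mean ± SD of 3 libraries, with Entrez gene identifiers and mm10 (GRCm38) coordinates.

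Spi1 transcripts rose at each step of the time course. Spi1 (ID 20375, chromosome 2, 91082374 to 91115759) stood at 62.5 ± 7.29 CPM in untreated cells and 109.6 ± 12 CPM at day 2. It reached 260.1 ± 14.1 CPM at day 4 and 458 ± 33.9 CPM at day 6. The ratios to untreated were 1.75, 4.16 and 7.33. All 3 libraries of each day lay above all 3 of the group before it. The log2 fold changes against untreated were 0.81 ± 0.11 (SE; edgeR quasi-likelihood adjusted p = 0.0039), 2.06 ± 0.11 (1.28e-07) and 2.87 ± 0.12 (2.79e-09). The exact two-sided permutation p was 0.1 at each day, the smallest that 3 against 3 libraries allow. Trp53 (ID 22059, chromosome 11, 69580348 to 69591873), the gene the labels give as deleted, had 42.8 ± 1.90 CPM in untreated cells. It had 42.1 ± 1.81 CPM at day 2, 30.0 ± 3.74 CPM at day 4 and 15.7 ± 1.62 CPM at day 6. The fall passed the edgeR quasi-likelihood test at day 4 (log2 fold change -0.51, adjusted p = 0.00274) and day 6 (-1.45, adjusted p = 4.57e-07). The exact permutation p for Trp53 was 0.7, 0.1 and 0.1. A count over the whole gene does not show which exons the reads came from, so it does not test the deletion.

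**Figure D1:**
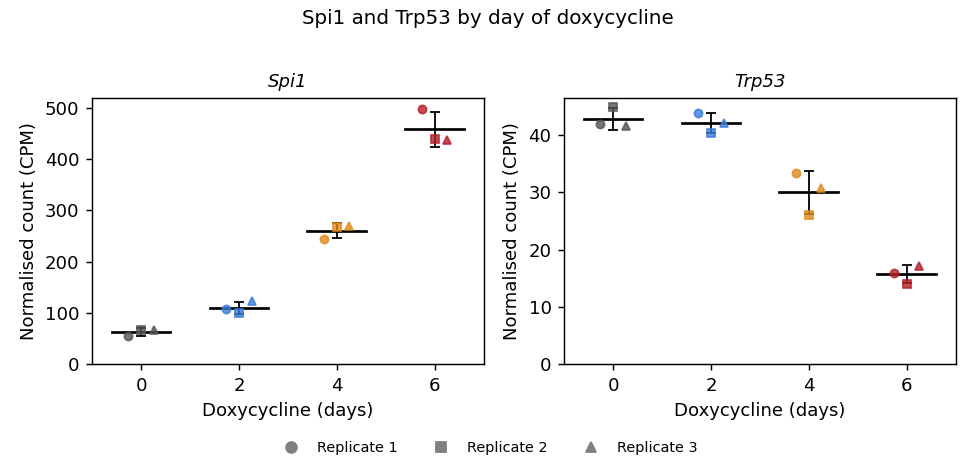
Normalised counts (CPM, y axis) of Spi1 and Trp53 against days of doxycycline (x axis) in the 12 libraries, with symbols for the replicates, a line at each group mean and bars of 1 SD (n = 3). Spi1 rose from a mean of 62.5 to 458 CPM and Trp53 fell from 42.8 to 15.7 CPM.

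The transcriptome moved in the same order as the days. The first principal component carried 71.0% of the variance, with scores of -67.2 to -54.7 in untreated libraries, -49.9 to -40.7 at day 2, 5.10 to 22.7 at day 4 and 79.2 to 98.4 at day 6. Of 12057 genes tested, 126 were higher and 49 lower at day 2 than in untreated cells. At day 4, 2667 were higher and 2440 lower, and at day 6, 4224 were higher and 3967 lower. Changes of at least 2-fold numbered 44 higher and 16 lower at day 2, 1044 and 642 at day 4, and 2032 and 1837 at day 6. A test over the 4 groups together called 8282 genes. Day 6 replicate 2 stood apart from the other libraries of its group. The variance of its counts against day 6 replicates 1 and 3 was 41.0 and 35.8 times that of counting error, compared with 4.53 between replicates 1 and 3 and 2.53 to 9.89 between pairs of the other groups. Without that library the calls were 378 higher and 225 lower at day 2, 3103 and 3040 at day 4, and 4416 and 4237 at day 6. Other omissions lowered the day 2 counts, to 27 and 11 without day 2 replicate 2, 36 and 12 without day 2 replicate 1, 30 and 22 without untreated replicate 1 and 80 and 23 without untreated replicate 3, and the lower count to 29 without day 2 replicate 3 and 32 without day 4 replicate 2. The share of calls that were higher depended on the scaling at the later days. At day 6 it was 51.6% with TMM factors, 37.3% with upper-quartile factors and 25.2% with library totals, which shifted the median of all genes by -0.25 and -0.51 on the log2 scale. At day 4 the share was 52.2%, 41.2% and 39.1%, with shifts of -0.09 and -0.12.

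**Figure D2:**
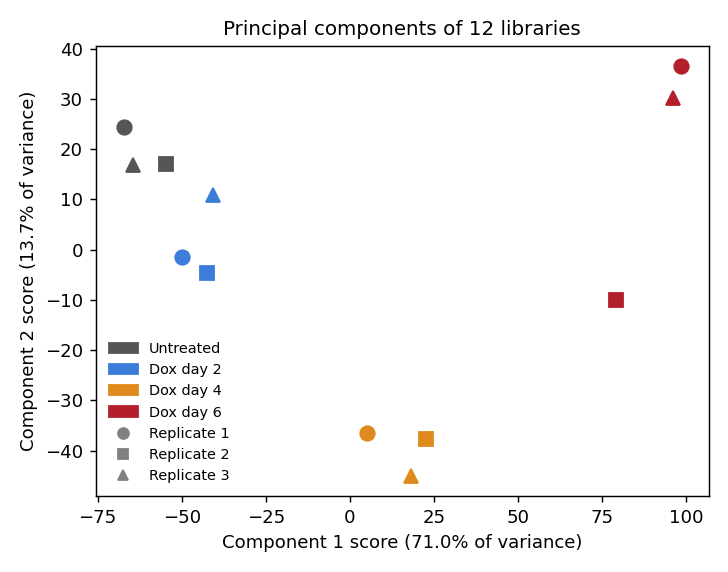
Scores of the 12 libraries on principal components 1 (x axis, 71.0% of the variance) and 2 (y axis, 13.7%), coloured by group with symbols for the replicates. The groups follow the days along component 1, and day 6 replicate 2, at 79.2, lies apart from the other day 6 libraries at 95.9 and 98.4. On component 2 that library lies between the day 4 libraries and the other day 6 libraries.

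The first comparison asked which genes moved within 2 days on Dox. Single receptor genes of myeloid cells rose and a small group of genes that untreated cells expressed fell. Lpl (ID 16956), which encodes lipoprotein lipase, rose from 14.5 ± 1.84 to 95.0 ± 26.9 CPM, and Gapt (ID 238875), a GRB2-binding membrane adaptor, rose from 4.29 ± 0.369 to 30.1 ± 6.70 CPM. Adgrg1 (ID 14766), an adhesion receptor of blood stem and progenitor cells, fell from 371 ± 92.1 to 56.9 ± 7.34 CPM. Plch2 (ID 269615), a phospholipase C, fell from 109, 30.3 and 153 CPM in the untreated libraries to a mean of 0.175 ± 0.303 CPM, a total of 4 counts. Of 24 tested genes of Toll-like and Fc receptors, 2 rose (12 adjusted over the list alone) and none fell, with a median log2 fold change of 0.40 (camera adjusted p = 3.13e-12). With an estimated correlation the adjusted p for that list was 0.181. The members called were Pirb, an inhibitory immunoglobulin-like receptor (3.72 ± 0.879 to 12.3 ± 1.99 CPM), and Clec7a, the beta-glucan receptor (26.7 ± 1.82 to 87.8 ± 10.6 CPM). Among 30 PU.1-regulated myeloid genes 4 rose (13 rose and 2 fell adjusted over the list alone), with a median of 0.37 (camera adjusted p = 4.02e-07, or p = 0.134 with an estimated correlation). Pirb, Csf2ra and the NADPH oxidase gene called at day 2 are among these 4, so they count in more than 1 list. Cytokine and growth factor receptors had 3 of 27 higher and 1 lower (9 and 2 adjusted over the list alone; camera adjusted p = 2.81e-05, or p = 0.181 with an estimated correlation). Csf2ra and Csf2rb2, subunits for the GM-CSF and IL-3 receptors, rose from 42.3 ± 4.11 to 73.4 ± 6.75 CPM and from 22.0 ± 4.73 to 56.5 ± 4.86 CPM. The lysosomal membrane gene Laptm5 and the class II antigen-loading gene H2-DMa also rose, to 989.6 ± 50.4 and 28.0 ± 3.73 CPM from 602 ± 44.0 and 15.4 ± 1.61 CPM.

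Other lists were called by camera at the preset correlation at day 2, with few or no single members past the test. With an estimated correlation 0 lists were called at day 2. Splits that mixed untreated and day 2 libraries called up to 18 lists, against 14 in the real split. These list calls therefore do not separate a shift with Dox from an arbitrary grouping. All 31 mitosis genes lay above untreated, with a median log2 fold change of 0.31 (camera adjusted p = 1.51e-10, or p = 0.449 with an estimated correlation), and none was called (0 adjusted over the list alone). Of 32 ribosome biogenesis genes 31 lay below untreated, none called (0 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 2.91e-05, or p = 0.610 with an estimated correlation). Of 43 ribosomal protein genes 39 lay below and 1 was called lower (1 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 2.50e-07, or p = 0.413 with an estimated correlation). Endoplasmic reticulum chaperones had 21 of 22 below untreated, none called (0 adjusted over the list alone; median -0.17, camera adjusted p = 0.00144, or p = 0.610 with an estimated correlation). Lysosome and NADPH oxidase lists were called higher, with 2 of 30 and 1 of 8 members called (6 and 4 adjusted over the list alone; camera adjusted p = 4.66e-07 and 7.09e-04, or p = 0.363 and 0.373 with an estimated correlation). Monocyte and macrophage genes were called higher as a list with 0 of 29 members called (6 adjusted over the list alone; camera adjusted p = 0.0011, or p = 0.602 with an estimated correlation), but not without untreated replicate 1 (0.0621). The stem and progenitor list and the oxidative phosphorylation list were called lower with 0 members called (0 adjusted over the list alone; camera adjusted p = 0.0303 and 0.0157, or p = 0.464 and 0.745 with an estimated correlation). The stem and progenitor call was lost without untreated replicates 1 or 2 or day 2 replicates 1 or 2 (camera adjusted p = 0.0661 to 0.157), and the oxidative phosphorylation call without untreated replicate 2 (0.292). Fry did not call the mitosis, ribosome biogenesis, chaperone, monocyte, stem and progenitor or oxidative phosphorylation lists at day 2 (adjusted p = 0.0820 to 0.363).

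Further genes with the largest rises at day 2 were Pld4, Pcdh18, Cfp, Cyp4f18, Zfp385a and Padi2. Pld4, an endolysosomal nuclease of myeloid cells, went from 8.54 ± 4.67 to 70.6 ± 23.0 CPM. The others reached 10.1 to 37.7 CPM, and Cfp encodes properdin of the complement system. Further genes with the largest falls were Sox6, Gstm5, Muc13, Gstm1, Ssbp2 and Heg1. Gstm1, a glutathione transferase whose family members share sequence, went from 413 ± 180.3 to 135 ± 14.3 CPM, and Ssbp2 from 69.4 ± 11.7 to 25.9 ± 1.2 CPM. The genes fixed for the study in advance had not passed the test by day 2 apart from Spi1. Csf1r, the receptor of macrophage colony-stimulating factor, had 88.0 ± 30.4 CPM untreated and 306 ± 70.1 CPM at day 2 (quasi-likelihood adjusted p = 0.0503). Mpo, Kit, Myc and Mki67 had quasi-likelihood adjusted p of 0.104, 0.588, 0.401 and 0.203. In each gene named here as changed at day 2, all 3 day 2 libraries lay on 1 side of all 3 untreated libraries. The naming rule required this of the 16 largest changes, and every named gene was called from the same libraries. Chance alone gives this arrangement in 10% of genes, so it is no separate support. Of the 16 genes with the largest changes, Gapt, Lpl, Pcdh18, Padi2, Plch2, Adgrg1 and Ssbp2 passed with each library left out. The other 9 lost the call under at least 1 omission, with quasi-likelihood adjusted p of 0.0518 to 0.184, most often without day 2 replicate 2 (9 genes), day 2 replicate 1 (8) or untreated replicates 1, 3 and 2 (6, 5 and 4), and in 1 to 3 genes without day 2 replicate 3, a day 4 library or day 6 replicate 1. Of all 32 named genes called at day 2, 17 lost the call under at least 1 omission (quasi-likelihood adjusted p = 0.0501 to 0.213), while Pirb, Clec7a, Csf2ra, Csf2rb2, Laptm5 and H2-DMa kept it under each.

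By day 4 many monocyte genes had risen. Genes of mature neutrophils (20 of 33 higher, 2 lower) and of secondary and tertiary granules (15 of 23, 1) had risen too. Csf1r (ID 12978) reached 817 ± 109 CPM against 88.0 ± 30.4 CPM untreated, and Ccr2 (ID 12772), the chemokine receptor of inflammatory monocytes, reached 633 ± 110.0 CPM against 34.7 ± 4.84 CPM. Of 29 tested monocyte and macrophage genes, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 2.20 (camera adjusted p = 3.23e-08). With an estimated correlation that p was 0.388. Fcgr1, the high-affinity IgG receptor, rose from 2.48 ± 2.44 to 245 ± 23.0 CPM, Ctss, a lysosomal protease, from 37.3 ± 15.5 to 1100.0 ± 146 CPM, and Ms4a6c from 13 ± 7.60 to 625 ± 65.2 CPM. The member that fell was Slpi, a secreted protease inhibitor, from 728 ± 11.4 to 417 ± 12.8 CPM. Of 30 PU.1-regulated myeloid genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 1.55 (camera adjusted p = 6.90e-12, or p = 0.0575 with an estimated correlation). Klf4, a factor of monocyte differentiation, rose from 9.77 ± 6.11 to 212 ± 30.2 CPM and Cd68 from 7.45 ± 1.33 to 104 ± 11.5 CPM, while Mpo, the myeloperoxidase of primary granules, fell from 18038 ± 1186 to 8011 ± 1766 CPM. Among 24 Toll-like and Fc receptors 22 rose and none fell (23 adjusted over the list alone; camera adjusted p = 9.55e-19, or p = 0.134 with an estimated correlation). Tlr8 and Tlr9, sensors of nucleic acids, went from 0.515 ± 0.398 to 21.8 ± 8.10 CPM and from 2.68 ± 1.35 to 87.3 ± 9.0 CPM. Adhesion and chemotaxis receptors had 16 of 24 higher and none lower (17 adjusted over the list alone; camera adjusted p = 7.37e-09, or p = 0.0575 with an estimated correlation), including Icam1 and Itgam, the latter from 28.7 ± 13.6 to 302 ± 89.1 CPM.

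Myeloid transcription factors went both ways at day 4, with 16 of 33 higher and 5 lower (17 and 5 adjusted over the list alone). The camera adjusted p was 0.0222, or p = 0.435 with an estimated correlation, and the call was lost without untreated replicate 2 (camera adjusted p = 0.0668). Irf5 rose from 8.49 ± 5.14 to 304 ± 44.3 CPM, and the macrophage factor Maf rose to 17.6 ± 5.93 CPM. Myb, a factor of myeloid progenitors, fell from 718 ± 35.4 to 301 ± 63.2 CPM and Runx2 from 109 ± 16.2 to 48.1 ± 3.56 CPM. Kit, the stem cell factor receptor, fell from 463 ± 7.47 to 139 ± 34.6 CPM and Myc from 277 ± 41.4 to 111 ± 29.6 CPM. Interferon response genes had 22 of 30 higher and none lower (24 adjusted over the list alone; camera adjusted p = 1.94e-06, or p = 0.595 with an estimated correlation). Oas3 rose from 34.0 ± 28.0 to 189.7 ± 4.42 CPM, and its untreated libraries stood at 13.9, 66.0 and 22.0 CPM. Lysosome genes had 25 of 30 higher and 2 lower (27 and 2 adjusted over the list alone; camera adjusted p = 1.51e-10, or p = 0.198 with an estimated correlation), with Psap at 5506 ± 785 CPM against 1553 ± 329.6 CPM. Ribosome biogenesis had 25 of 32 genes lower and none higher (26 adjusted over the list alone; camera adjusted p = 2.50e-08, or p = 0.515 with an estimated correlation). Srm, which makes spermidine, fell from 254 ± 26.9 to 112 ± 24.1 CPM and Gnl3, nucleostemin, from 122 ± 4.85 to 54.3 ± 10.5 CPM. Ribosomal protein genes had 34 of 43 lower and none higher (35 adjusted over the list alone; camera adjusted p = 9.62e-09, or p = 0.373 with an estimated correlation). Mitosis genes had 25 of 31 higher and none lower (27 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 2.81e-05, or p = 0.610 with an estimated correlation), and Kif23, a kinesin of cytokinesis, went from 36.7 ± 5.50 to 88.8 ± 7.63 CPM.

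The largest rises at day 4 among genes of at least 10 CPM were those of Clec10a, Ptpro, Pgap1, Fcgr1, Rnd3, Clec4a3, Clec4a1 and Lilra6. Their day 4 means were 13.9 to 245 CPM and their untreated means 0.0473 to 2.48 CPM. Clec4a3, Clec4a1 and Lilra6 belong to families of close paralogs, so reads may be shared among their members. The largest falls were those of Plch2, Ppl, Sox6, Eln, Hspa1b, Hspa1a, Gstm5 and Serpinh1. Serpinh1, the collagen chaperone, fell from 72.2 ± 45.2 to 4.08 ± 0.135 CPM, and Eln, elastin, fell from 24.3 ± 10.9 CPM to a total of 12 counts. The falls of Hspa1a and Hspa1b, inducible heat shock proteins, rested on untreated replicate 3, at 73.1 and 112 CPM against 4.04 to 9.19 CPM in the other untreated libraries. Without it the log2 fold change of Hspa1a went from -4.37 to -1.94, and Hspa1b lost its call (quasi-likelihood adjusted p = 0.0679). Without day 4 replicate 2 both lost it (0.0547 for Hspa1b and 0.0508 for Hspa1a). Csf3r, Cebpa and Mki67 passed at day 4 with log2 fold changes of 0.47, -0.52 and 0.63, but Csf3r lost the call without untreated replicates 1 or 2 or day 4 replicate 1 (quasi-likelihood adjusted p = 0.0510 to 0.0603). Cebpa lost it without day 4 replicate 2 (0.0576), its log2 fold change being -0.31 without untreated replicate 3, and Mki67 lost it without day 4 replicate 3 (0.0580).

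**Figure D3:**
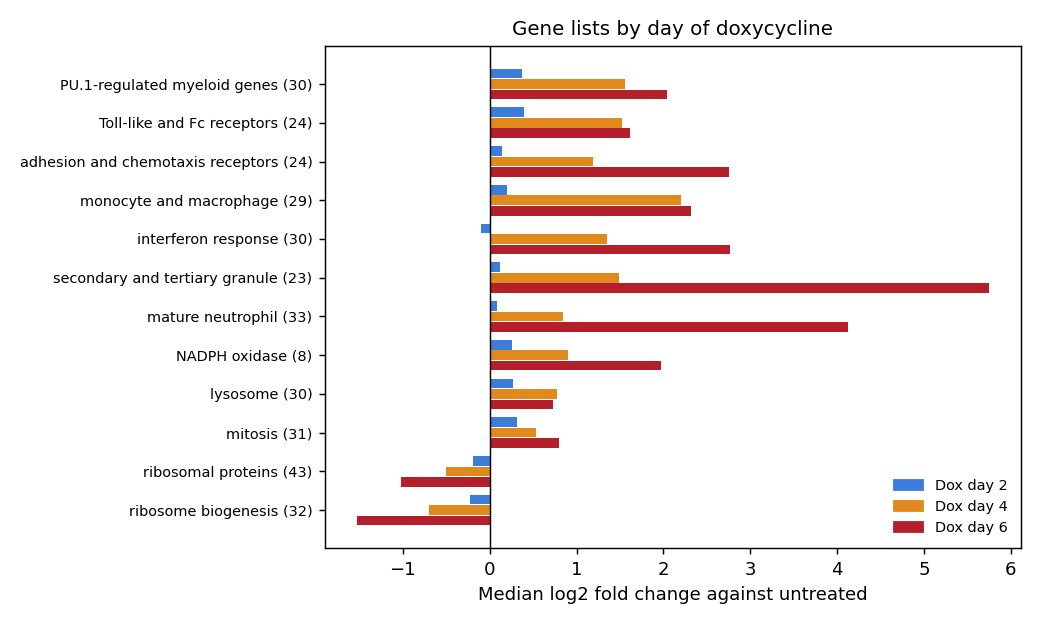
Median log2 fold change against untreated (x axis) of 12 gene lists (y axis, tested members in brackets) at days 2, 4 and 6, each bar the median over the members of a list. The granule list went from 1.49 at day 4 to 5.75 at day 6, while the median of ribosome biogenesis reached -1.53; a bar does not show whether a list passed its test.

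At day 6 the granule genes of maturing neutrophils rose to high levels. Ltf (ID 17002, chromosome 9, 111019292 to 111042766), which encodes lactoferrin, went from 77.1 ± 50.2 CPM untreated and 115 ± 38.9 CPM at day 4 to 9392 ± 3765 CPM. S100a8 and S100a9, the subunits of calprotectin, reached 17754 ± 6025 and 40784 ± 15488 CPM from 249 ± 153 and 229 ± 129 CPM. Of 23 tested secondary and tertiary granule genes, 22 rose and 1 fell (22 and 1 adjusted over the list alone), with a median log2 fold change of 5.75 (camera adjusted p = 1.85e-15). With an estimated correlation that p was 0.181. Camp, the cathelicidin, reached 6374 ± 2087 CPM, Ngp 26495 ± 11627 CPM, Mmp9, a gelatinase, 2645 ± 277 CPM, and Chil3 12572 ± 1506 CPM. The summed level of the list was 122282, 67609 and 108416 CPM in day 6 replicates 1, 2 and 3, against 3504 to 4283 CPM untreated. Of 33 mature neutrophil genes, 30 rose and 1 fell (30 and 1 adjusted over the list alone; camera adjusted p = 3.03e-15, or p = 0.134 with an estimated correlation). Their summed level was 87069, 45129.7 and 80569 CPM in the 3 day 6 libraries. Fpr2, a formyl peptide receptor, rose from 2.44 ± 1.38 to 243 ± 7.37 CPM with 249, 235 and 246 CPM in the 3 libraries, and Fpr1 rose from 1.22 ± 1.12 to 125 ± 5.69 CPM. Ly6g, the neutrophil surface marker Ly6G, rose from 1.17 ± 0.940 to 63.5 ± 6.74 CPM, and Il1r2, the decoy IL-1 receptor, from 6.74 ± 0.494 to 118 ± 19.8 CPM. Cebpe (ID 110794), the factor of granulocyte maturation, rose from 67.1 ± 4.65 to 520.4 ± 169 CPM, with 645, 328 and 589 CPM in replicates 1, 2 and 3. Csf3r, the G-CSF receptor, rose from 274 ± 23.3 to 731 ± 163 CPM. The 10 most abundant genes of each library took 15.6%, 9.63% and 14.2% of the counts at day 6, against 4.84% to 6.18% in the earlier libraries.

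All 8 NADPH oxidase genes rose at day 6 (8 adjusted over the list alone; camera adjusted p = 3.46e-08, or p = 0.153 with an estimated correlation). Cybb, the catalytic subunit, reached 3807 ± 1039 CPM from 106 ± 40.4 CPM. Adhesion and chemotaxis receptors had 20 of 24 higher and 1 lower (20 and 1 adjusted over the list alone; camera adjusted p = 2.13e-10), and Itgam, the CD11b integrin, reached 2276 ± 734 CPM. This list at day 6 was the only call at any day that also passed with an estimated correlation (adjusted p = 0.0466). Lyz2, lysozyme, rose from 1087 ± 193 to 24305 ± 5082 CPM. The largest rises among genes of at least 10 CPM were Csta3, Stfa2, Ceacam10, Stfa2l1, Cstdc4, Clec4a2, Stfa3 and Asprv1. Csta3, Stfa2, Stfa2l1, Cstdc4 and Stfa3 are neighbouring stefin A genes on chromosome 16 with close sequences, so the division of reads among them is uncertain. Csta3 had 0 counts in the 3 untreated libraries and 61.6, 21.7 and 2.93 CPM in the day 6 libraries. Their mean was at least 66.7-fold above a floor of 3 counts per library, and 28.6-fold without day 6 replicate 1. Ceacam10 went from 0.284 ± 0.145 to 119.7 ± 43.6 CPM. The primary granule list went both ways, with 4 of 11 higher and 6 lower (4 and 6 adjusted over the list alone), and was not called by camera (adjusted p = 0.0812). By fry it was called lower (adjusted p = 0.00329), and its summed level was 11256 ± 1340 CPM against 31397 ± 2256 CPM untreated. Mpo fell to 4169.8 ± 425 CPM, Elane, neutrophil elastase, from 5072 ± 528 to 2212 ± 541 CPM, and Ctsg, cathepsin G, from 4312 ± 223 to 729 ± 105 CPM. Ms4a3 and Igsf6 rose, to 489 ± 107 and 1016 ± 309.7 CPM.

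The monocyte genes differed between the day 6 libraries. Of 29 monocyte and macrophage genes, 21 rose against untreated and 5 fell (21 and 5 adjusted over the list alone), with a median log2 fold change of 2.32 (camera adjusted p = 0.0214, or p = 0.695 with an estimated correlation). Their summed level was 8349.5, 16858 and 8799 CPM in day 6 replicates 1, 2 and 3, against 17190.1 to 19741 CPM at day 4 and 7918 to 10419.9 CPM untreated. Csf1r had 284, 727 and 303 CPM in the 3 day 6 libraries, Fcgr1 had 115, 514 and 130.4 CPM, and Ccr2 had 264, 773 and 327 CPM. Irf8, a factor of monocyte commitment, fell from 711 ± 228 to 145 ± 77.3 CPM, with 102, 235 and 99.6 CPM, and Cd163 fell from 21.2 ± 2.82 to 3.24 ± 1.29 CPM. Interferon response genes had 27 of 30 higher and 1 lower (27 and 1 adjusted over the list alone; camera adjusted p = 2.70e-06, or p = 0.595 with an estimated correlation). Their summed level was 10190.1, 14664 and 9778 CPM in the day 6 libraries, against 1400.1, 3025 and 1711 CPM in the untreated ones. Oas3 reached 903 ± 150.1 CPM and Oas2 391 ± 34.3 CPM, while Ifit3 had 113, 469.8 and 110.1 CPM. Gbp3 was the member that fell, from 67.9 ± 9.85 to 26.6 ± 7.57 CPM. The 7 tested class II genes all rose (7 adjusted over the list alone; camera adjusted p = 0.0343, or p = 0.464 with an estimated correlation), with Cd74, the invariant chain, at 58.2 ± 31.1 CPM against 4.24 ± 0.574 CPM. Without replicate 2, 20 monocyte genes were higher and 6 lower at day 6, 25 interferon genes were higher and 1 lower, and 22 secondary and tertiary granule genes were higher and 1 lower.

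**Figure D4:**
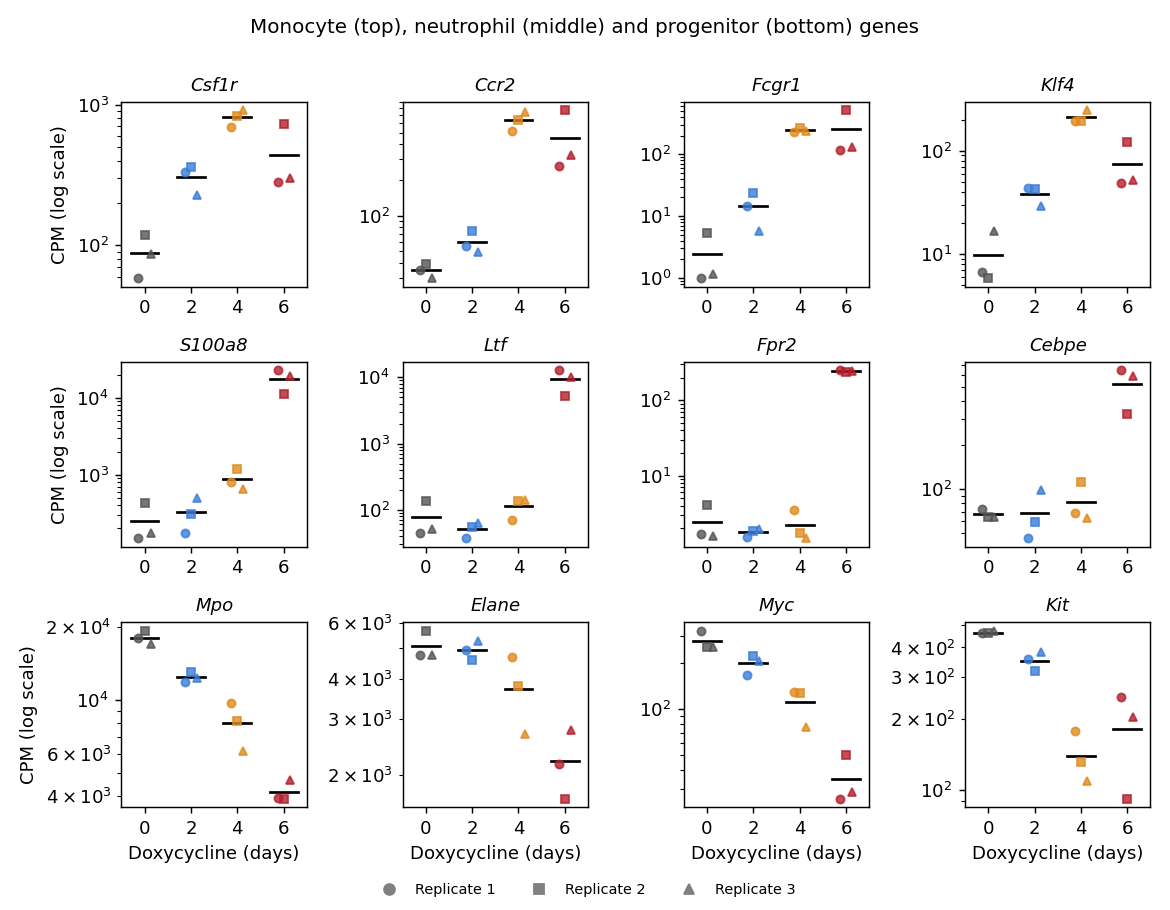
CPM on a log scale (y axis) of 12 genes against days of doxycycline (x axis), with symbols for the replicates and a line at each group mean. The monocyte genes of the top row are highest in day 6 replicate 2 within their day (Csf1r 727 CPM), the neutrophil genes of the middle row rise at day 6 (Fpr2 to 243 CPM), and Mpo, Elane and Myc of the bottom row fall.

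Genes of cell growth lay further below untreated at day 6 than at day 4, while genes of mitosis lay above it. Lists were tested only against untreated, not for the step from day 4 to day 6. Myc (ID 17869) fell to 35.1 ± 13.3 CPM, and Mxd1, a partner of Max that opposes Myc at its target genes, rose from 46.8 ± 6.16 to 524 ± 66.3 CPM. All 32 tested ribosome biogenesis genes fell (32 adjusted over the list alone), with a median log2 fold change of -1.53 (camera adjusted p = 1.94e-13, or p = 0.398 with an estimated correlation). Srm fell to 42.1 ± 19.9 CPM, Gnl3 to 23.0 ± 6.50 CPM and Ppan to 16.0 ± 3.95 CPM. Ribosomal protein genes had 41 of 43 lower and none higher (42 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 3.32e-11, or p = 0.225 with an estimated correlation). Of 13 genes of the mitochondrial genome, 12 fell (12 adjusted over the list alone; camera adjusted p = 0.00654, or p = 0.602 with an estimated correlation), and mt-Nd1 went from 1567 ± 71.2 to 823 ± 28.5 CPM. Mitosis genes had 30 of 31 higher and none lower (30 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 2.35e-04, or p = 0.660 with an estimated correlation). With library totals the median of the mitosis list was 0.27, with 15 higher and 1 lower. DNA replication genes had 5 of 37 higher and 14 lower at day 6 (5 and 14 adjusted over the list alone), with a median of -0.20, and were not called (camera adjusted p = 0.135, or p = 0.785 with an estimated correlation). That list was called lower with upper-quartile factors (5 higher and 27 lower, median -0.45, camera adjusted p = 0.049999), with library totals (2 and 31, -0.72, camera adjusted p = 0.00789) and without a low-count filter (camera adjusted p = 0.0413). Mki67 rose from 673 ± 23.3 to 1486 ± 389 CPM, with 1615, 1049 and 1793 CPM in day 6 replicates 1, 2 and 3. Cdk4 and Cdk6, kinases of G1 phase, fell from 326 ± 28.3 to 77.9 ± 16.1 CPM and from 237 ± 17.7 to 47.3 ± 11.1 CPM, while Ccnd3 rose from 154 ± 33.2 to 624 ± 117 CPM. Their list of cyclin-dependent kinase regulators had 10 of 17 higher and 2 lower (10 and 2 adjusted over the list alone). It was not called by camera (adjusted p = 0.0857) and was called higher by fry (adjusted p = 1.36e-04). Cebpa fell from 472 ± 113 to 167 ± 18.5 CPM, Bcl2, a survival gene, from 51.0 ± 2.60 to 6.36 ± 2.52 CPM, and Kit to 181 ± 80.4 CPM. Cd34, Gfi1 and Cdkn1a did not pass at day 6, with quasi-likelihood adjusted p of 0.255, 0.890 and 0.103. The largest falls were those of Eln, Serpinh1, Col16a1, Plch2, Adamts9, Ppl, Smoc2 and Adgrg1, all below 1 CPM at day 6 except Adgrg1, which had 371 ± 92.1 CPM untreated and 6.07 ± 0.467 CPM at day 6. Smoc2 had 2.73 CPM in day 6 replicate 2 and 0 and 0.195 CPM in the other day 6 libraries, and its log2 fold change against untreated went from -6.35 to -9.56 without replicate 2. Of the named genes called against untreated, the 3 libraries of the day lay on 1 side of all 3 untreated libraries in 122 of 125 at day 4 (not in Mmp9, Dhcr7 and Ddit4) and in 133 of 136 at day 6 (not in Sparc, Pfkp and Pfkfb3). The largest changes were chosen for this arrangement, so these counts are no separate support.

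Genes changed in both steps between days. From day 2 to day 4, 1812 genes rose and 1230 fell, and from day 4 to day 6, 2851 rose and 2726 fell. The 1230 became 716, 722, 581, 621 and 1882 without day 2 replicates 1 or 3, day 4 replicates 2 or 3 or day 6 replicate 2. With upper-quartile factors and with library totals the higher share fell from 59.6% to 43.8% and 35.1% for the first step and from 51.1% to 34.6% and 17.5% for the second. Of the genes higher at day 4 than untreated, 1118 rose again by day 6, 1157 were not called in the second step and 392 fell. Of the genes lower at day 4, 1122 fell again, 1141 were not called in the second step and 177 rose. Another 1556 genes rose and 1212 fell from day 4 to day 6 without a call at day 4. Rnase6 and Siglec1 were among the largest rises of the first step, from 0.527 ± 0.180 to 47.3 ± 7.79 CPM and from 0.412 ± 0.177 to 25.4 ± 11.2 CPM, as was Galnt9, which reached 5.7, 10.6 and 13.8 CPM in the day 4 libraries from at most 0.15 CPM at day 2. Serpinh1, Col16a1 and Smoc2 were the largest falls. Fpr2, AA467197 and Slc6a12 rose most in the second step, and Tns1, a focal adhesion protein, fell from 237, 172 and 191 CPM in the day 4 libraries to 12.2 ± 2.39 CPM, and Fgfr2 from 17.4 ± 6.40 to 1.15 ± 0.899 CPM. Lpl fell in the second step from 597 ± 91.2 to 155 ± 30.8 CPM, H2-DMa from 87.9 ± 6.98 to 37.2 ± 1.62 CPM, Klf4 from 212 ± 30.2 to 73.7 ± 41.4 CPM and Psap from 5506 ± 785 to 2906 ± 707 CPM. Csf1r fell short of the test in this step (log2 fold change -0.90, quasi-likelihood adjusted p = 0.0675). A rise at day 2 followed by a fall to day 6 was called for 4 genes, Pcdh18, Arl5c, Pacc1 and Gprc5c, and the opposite for 3, Msl2, Ddit4 and Gnai3. Gprc5c lay outside the rule for named genes and was chosen after its values were seen. Pcdh18, a protocadherin, had 3.21 ± 0.336, 16.5 ± 5.23, 40.1 ± 8.78 and 5.06 ± 2.48 CPM over the 4 groups. The transient counts ranged from 1 and 1, without untreated replicates 1 or 3 or day 2 replicates 1 or 2, to 30 and 32 without day 6 replicate 2, and the day 2 calls of Arl5c, Pacc1, Ddit4 and Gnai3 each depended on 7 or more of the 12 libraries. All 126 genes higher and 49 lower at day 2 were called in the same direction at day 4, where independent sets would share 27.9 and 9.92. Of them, 123 and 47 were also called at day 6, against 44.1 and 16.1. Between day 4 and day 6, 2291 higher and 2148 lower genes were shared, against 934 and 803 for independent sets. These comparisons share the same 3 untreated libraries, which are too few to split. In data simulated with no effect, equally many genes taken by p shared on average 97.9 and 37.4 between day 2 and day 4, 109.95 and 41.75 between day 2 and day 6, and 1676 and 1462 between day 4 and day 6. Part of the overlap may therefore come from the shared untreated libraries.

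Further lists were called higher at day 4 and day 6. At day 4 these were secondary and tertiary granule genes (15 of 23 higher, 1 lower), mature neutrophil genes (20 of 33, 2), cytokine and growth factor receptors (15 of 27, 4), NADPH oxidase (8 of 8, 0), inflammatory genes (15 of 23, 2) and class II genes (5 of 7, 0). Adjusted over the list alone the counts were 16 and 1, 23 and 2, 15 and 5, 8 and 0, 16 and 2, and 7 and 0 (camera adjusted p = 1.94e-06 to 1.45e-04, or p = 0.153 to 0.506 with an estimated correlation). Immediate early and heat shock genes had 7 of 22 higher and 3 lower and the BCL2 family 8 of 12 and 1 (7 and 3, and 8 and 2, adjusted over the list alone; camera adjusted p = 0.0183 and 0.0372, or p = 0.610 and 0.381 with an estimated correlation). The first call was lost without untreated replicates 1 or 2 or day 6 replicate 2 (camera adjusted p = 0.0586 to 0.0983) and the second without any 1 library except untreated replicate 3 (0.0536 to 0.1). At day 6, PU.1-regulated myeloid genes (24 of 30 higher, 3 lower), myeloid transcription factors (19 of 33, 7), cytokine receptors (20 of 27, 5), Toll-like and Fc receptors (19 of 24, 0), inflammatory genes (16 of 23, 3) and lysosome genes (21 of 30, 2) were called higher, with the same counts adjusted over the list alone (camera adjusted p = 3.48e-08 to 0.0115, or p = 0.0907 to 0.472 with an estimated correlation). With library totals the counts were 14 higher and 10 lower for the transcription factors (median 0.06 against 0.57 with TMM factors), 12 and 5 for cytokine receptors (0.46 against 1.00), 14 and 5 for inflammatory genes (0.74 against 1.23) and 14 and 5 for lysosome genes (0.23 against 0.73). Oxidative phosphorylation had 20 of 33 lower and none higher (20 adjusted over the list alone; camera adjusted p = 0.0228, or p = 0.754 with an estimated correlation), and lost the call without untreated replicate 2 (0.0647) or day 6 replicate 3 (0.0522). Its median was -0.35, with 28 lower for upper-quartile factors (median -0.60) and 32 for library totals (-0.86).

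Markers of other marrow cell types were measured in the same libraries. Eosinophil genes varied between libraries of a day, with summed levels of 95.7 to 118 CPM untreated, 58.2, 132 and 295 CPM at day 2, 139, 1344 and 724 CPM at day 4 and 889, 444 and 811 CPM at day 6. Of the sums at day 6, 645, 328 and 589 CPM came from Cebpe, which also stands in other lists, against 64.3 to 72.5 CPM of the untreated sums. At day 4, 8 of 10 rose (8 adjusted over the list alone), with Prg2, the eosinophil major basic protein, at 35.3, 676 and 383 CPM in replicates 1, 2 and 3. The camera adjusted p was 0.0433, or p = 0.695 with an estimated correlation, and this call was lost when any of 7 libraries was left out, the 3 untreated ones, day 4 replicate 2 and the 3 of day 6 (camera adjusted p = 0.0528 to 0.106). Dendritic cell genes summed to 831 to 1261 CPM untreated and 346, 680.4 and 323 CPM at day 6, a fall carried mostly by Irf8. Of 7 tested dendritic genes 4 rose and 2 fell at day 6 (4 and 2 adjusted over the list alone), with a median of 1.17. Without day 6 replicate 2, 3 dendritic genes rose and 3 fell, with a median of 0.29. Megakaryocyte genes summed to 26.7 to 35.6 CPM untreated and 121, 64.3 and 117 CPM at day 6. Erythroid genes summed to 67.8 to 228 CPM and B cell genes to 21.1 to 134 CPM over the 12 libraries. T and NK cell genes summed to 10.2 to 12.6 CPM untreated and 69.7 to 103 CPM at day 6, of which Thy1 made 37.3 ± 6.37 CPM. Stromal genes summed to 204 to 299.7 CPM untreated and 52.1 to 107.7 CPM at day 6. The dendritic, megakaryocyte and B cell lists were not called by camera at any day (adjusted p = 0.166 to 0.944). Fry called the B cell list lower at day 4 (adjusted p = 0.0186) and day 6 (2.31e-04) and the dendritic list higher at day 4 (0.0149).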

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

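The tests that weigh explanations in this part were chosen after the results were seen.

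Some genes moved in opposite directions at day 4 and day 6 against untreated, with a called change between the days. There were 30 genes higher at day 4 and lower at day 6, and 42 genes lower at day 4 and higher at day 6. The counts depended on the scaling, with 29 and 44 for RLE factors, 48 and 46 for upper-quartile factors and 86 and 38 for library totals. Among the genes within the naming rule, the log2 fold change from day 4 to day 6 was -4.38 for Sparc, whose group means were at or below 1.67 CPM throughout. It was -1.87 for Arl5c, which had 77.0 ± 11.7 CPM at day 4 and 21.2 ± 2.97 CPM at day 6. It was -1.28 for the phosphofructokinase Pfkp, at 309.9 ± 33.3 and 127 ± 23.9 CPM. For Pfkfb3, which makes an activator of phosphofructokinase, it was 0.83, at 99.4 ± 10.8 and 177 ± 35.9 CPM. The day 6 calls of Sparc, Pfkp and Pfkfb3 against untreated were lost on leaving out 8, 8 and 4 of the 12 libraries (quasi-likelihood adjusted p = 0.0521 to 0.170, 0.0555 to 0.169 and 0.104 to 0.149), and their day 6 and untreated libraries overlapped.

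Day 6 replicate 2 carried more transcripts of monocytes, macrophages and the interferon response and fewer of secondary and tertiary granules than the other day 6 libraries. A day 4 library under a day 6 label is argued against, since at least 49.2% of the genes that separate the days lay nearer to the other day 6 libraries, compared with 3.69% to 4.95% for true day 4 libraries. For this each day 4 library in turn was held out with day 6 replicate 2 from the choice of genes, a reference added after first cutoffs had left the value undecided. In this library 58 genes of at least 10 CPM exceeded the highest of the other 5 day 4 and day 6 libraries by over 2 times. Each of those libraries had 1 to 7 such genes. Levels between those of day 4 and day 6 do not account for these 58 genes. Genes that peak between the days would also exceed both. The count therefore does not decide whether the cells were partway between the day 4 and day 6 states. Of the genes that separate the days, 49.2% to 52.6% lay nearer to the other day 6 libraries. On principal component 2 the library lay between the day 4 and the other day 6 libraries. On component 3 (3.62% of the variance) it lay outside both, at 38.7. The other day 6 libraries had -13.2 and -10.3 there, and the day 4 libraries -8.33 to -5.18. Another mix of cells in that sort and a stronger interferon exposure of that sample stay open, as does a partway state, alone or beside either. No biological explanation was tested, since the design names no group that would separate them.

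Eosinophil genes differed between the day 4 libraries, with Prg2 at 35.3, 676 and 383 CPM, Alox15 at 8.55, 160.2 and 93.5 CPM and Epx at 8.55, 138 and 61.8 CPM in replicates 1, 2 and 3. Of 10 tested members 8 had the same order over the 3 libraries, an order taken from the values seen. The exceptions were Siglecf and Cebpe, and Cebpe stands in 2 other lists too. A varying share of 1 kind of cell that carries these transcripts may account for this. The shared order does not separate it from a joint change of these genes within cells. Reads shared between the near-identical Ear genes are argued against by a median ratio of 16.1 between replicates 2 and 1 over the 7 members outside that family. The gate moved to low GFP with the days, and how far it removed cells that do not derive from the leukemia was not tested. If cells of that kind were sorted, it stays open whether they were leukemic. No group of the design separates these libraries, so no biological explanation was tested.

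The mitosis list was higher at day 6, with a median log2 fold change of 0.80, while ribosome biogenesis was lower, with -1.53. The TMM scaling carried much of the size of the mitosis median, which was 0.27 with library totals, with 15 higher and 1 lower. After a trend with gene length and level was taken away it was 0.58. The median thus stayed above 0 under both. Its spreads, 0.059 and 0.060, were computed over the 31 members as if these were independent, and not over libraries. With an estimated correlation the list was not called (camera adjusted p = 0.660). The spreads therefore do not exclude the scaling or the trend as the whole of the rise. The DNA replication list went the other way at day 6, with 5 of 37 higher and 14 lower, or 2 and 31 with library totals, so it stays open whether more cells were cycling, and no biological explanation was tested. Day 6 replicate 2 had the lowest summed mitosis level of its day, 4791 CPM against 7103 and 7184 CPM.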

How the results depend on the processing

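The settings of this part were all chosen before the values were seen. The direction of Spi1 and its call at days 4 and 6 held under all settings run, and its log2 fold changes with a library left out were 0.72 to 0.88, 1.96 to 2.11 and 2.78 to 2.93 at days 2, 4 and 6. At day 2 the call was lost against a 1.5-fold threshold with glmTreat (log2 fold change 0.81, adjusted p = 0.921), which asks for a larger change by its construction. That threshold left 7 higher and 4 lower genes at day 2, 986 and 505 at day 4, 2362 and 2021 at day 6, 462 and 153 from day 2 to day 4, and 972 and 621 from day 4 to day 6. DESeq2 called 281 higher and 143 lower genes at day 2, and 9 and 17 transient genes (up then down, down then up), and the cause was not tested. Fits of only the groups compared called 241 and 171 genes at day 2, 2002 lower genes from day 2 to day 4 and 4 lower lists at day 4, on fewer samples by construction. Library totals gave 2283 higher and 6764 lower genes at day 6, 2312 lower from day 2 to day 4, 1331 higher and 6263 lower from day 4 to day 6, and 16 and 0 transient genes, and upper-quartile factors gave 1897 lower from day 2 to day 4, in step with the shift of all genes that these scalings make. With an estimated correlation camera called 0 higher and 0 lower lists at day 2, 0 and 0 at day 4, and 1 and 0 at day 6. Fry called 1, 4 and 8 lower lists at days 2, 4 and 6, and the cause was not tested. Leaving out a library gave 27 (without day 2 replicate 2) to 378 (without day 6 replicate 2) higher and 11 to 225 lower genes at day 2, from the same libraries. It gave 2173 to 3103 and 1670.0 to 3040.0 at day 4, 3960.0 to 4416 and 3663 to 4237 at day 6, 1268 to 2311 and 581 (without day 4 replicate 2) to 1882 (without day 6 replicate 2) from day 2 to day 4, and 2308 to 3422 and 1988 to 3431 from day 4 to day 6. The count over 4 groups ranged from 7513 to 9149, and the transient counts from 1 to 30 and 1 to 32, lowest without untreated replicate 1 among others and highest without day 6 replicate 2. Lists ranged from 6 to 11 higher and 4 to 5 lower at day 2, 13 to 17 and 2 to 3 at day 4, and 14 to 15 and 3 to 5 at day 6. Results that turned direction were Pfkfb3 at day 6 (-0.15 with library totals), Laptm5 and Msl2 from day 4 to day 6 (-0.10 and -0.00655 with library totals), and Clec4a3 in that step (0.07 and not called with all libraries, -0.87 without day 6 replicate 2, up to 0.41 without day 6 replicate 1). Among lists, neither called at day 2 with all libraries, immediate early and heat shock genes turned to higher without untreated replicate 3 (camera adjusted p = 0.0319), and so did interferon response genes without untreated replicate 2 (camera adjusted p = 2.48e-05). With a minus sign for lower, the omissions ran from -0.969 (without day 2 replicate 2) for the first list, and from -0.572 (without day 4 replicate 3) to 0.301 (without day 2 replicate 3) for the second, which was called lower without untreated replicate 1 (camera adjusted p = 0.00167). For the named genes 370 gene and comparison values lost their call and 79 gained one over the omissions, against 8250 on their side of the threshold, and over the other settings 265 lost and 104 gained, against 6820. At the depths here levels of 0.393 to 0.640 CPM rest on 3 counts. Of planted 1.5-fold changes 28% to 32% were recovered in simulated data, in which depth was not varied and only 200 genes changed.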

Other observations

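The test of the Plch2 neighbourhood and the genes singled out in day 6 replicate 2 were chosen after the results were seen.

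Metabolic and stress genes moved in both directions at day 6. Slc2a3, a glucose transporter of neutrophils, rose from 20.7 ± 0.866 CPM untreated to 598 ± 136 CPM, Pfkfb4 from 42.9 ± 3.90 to 182 ± 31.8 CPM and Hk2, hexokinase 2, from 131 ± 12.7 to 256 ± 26.5 CPM. Pdk1 fell from 127 ± 0.456 to 44.9 ± 7.70 CPM and Pfkm, the muscle phosphofructokinase, from 34.5 ± 6.68 to 8.01 ± 1.69 CPM. The glycolysis list had 9 of 21 higher and 7 lower (9 and 7 adjusted over the list alone) and was not called (camera adjusted p = 0.614), and its median of 0.21 was -0.04 with upper-quartile factors and -0.32 with library totals. Sterol synthesis had 7 of 23 higher and 7 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.399), with Dhcr7, the last enzyme of cholesterol synthesis, at 23.7 ± 0.996 CPM against 71.0 ± 9.75 CPM, and Msmo1 at 54.6 ± 18.6 CPM against 27.9 ± 3.82 CPM. The sterol median was -0.25, and 0.07 without day 6 replicate 2, with 1 higher and 9 lower for upper-quartile factors (median -0.50) and 1 and 13 for library totals (-0.78). Of 22 immediate early and heat shock genes, 8 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.0641), with a median of 0.36 that was -0.16 with library totals. Without day 6 replicate 2 the median of this list was 0.18 (23 tested, camera adjusted p = 0.233). By fry it was called higher with all libraries (adjusted p = 0.00308). Btg2, an antiproliferative gene, rose from 10.3 ± 1.68 to 147 ± 8.21 CPM and Klf6 from 97.5 ± 17.4 to 469 ± 47.5 CPM.

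Single genes of the BCL2 family, of the p53 targets and of stromal cells also changed. The BCL2 family had 5 of 12 genes higher and 2 lower at day 6 (5 and 2 adjusted over the list alone; camera adjusted p = 0.532), with a median of 0.09 that was -0.16 with upper-quartile factors and -0.42 with library totals. Without day 6 replicate 2 the median of the family was -0.055 (13 tested). By fry it was called higher with all libraries (adjusted p = 0.00454). Mcl1, a survival gene of neutrophils, rose from 334 ± 32.0 to 1000.2 ± 126 CPM, and Bmf and Bcl2l11, which promote cell death, rose to 82.9 ± 20.6 and 71.9 ± 25.7 CPM from 32.5 ± 12.2 and 34.3 ± 10.8 CPM. Of 20 targets of p53, a factor the cells lack by their labels, 8 rose and 7 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.337), with a median of -0.05, a mean of 0.11 and a test direction of higher. By fry these targets were called higher (adjusted p = 0.00149). Upper-quartile factors gave 5 higher and 9 lower p53 targets (median -0.29) and library totals 4 and 11 (-0.55). Trp53inp1 rose from 42.4 ± 11.8 to 367 ± 56.1 CPM and Mdm2 from 57.9 ± 2.61 to 137 ± 14.5 CPM. Of 4 stromal marker genes with enough counts, 3 fell and 1 rose, too few to test as a list. Pdgfrb, a receptor of mesenchymal cells, fell from 196 ± 47.2 to 5.65 ± 1.93 CPM, and Cxcl12 from 42.9 ± 10.4 to 3.47 ± 0.892 CPM. The stem and progenitor list had 3 of 16 higher and 8 lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.176), with Hlf at 5.23 ± 0.0993 CPM against 20.7 ± 5.05 CPM and Erg at 52.0 ± 26.3 CPM against 4.57 ± 1.34 CPM. By fry that list was called lower at day 4 (adjusted p = 0.0221) and day 6 (adjusted p = 0.00819).

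Genes above the other day 4 and day 6 libraries in day 6 replicate 2 included C1qa, C1qb and C1qc, subunits of complement C1q made by macrophages, at 78.0, 52.6 and 89.7 CPM against at most 10.4, 7.03 and 11.5 CPM in the other 5. Siglec1, a sialic acid receptor of macrophages, had 162 CPM against at most 36.2 CPM, Apoe had 1900.2 CPM against 695 CPM and the interferon gene Ifit3 had 469.8 CPM against 113 CPM.

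Plch2 (chromosome 4, 154983115 to 155064091) fell to near 0 by day 2, and its untreated level varied between libraries. Of 8 tested genes within 200 kb, 0 were called lower at day 2, with log2 fold changes of -0.53 to 0.11, so none fell as Plch2 did. A smaller effect on the neighbourhood of the locus is not excluded. The lowest values, -0.53 and -0.51, had SE of 0.35 and 0.47, and only day 2 was tested. What shut Plch2 off was not tested further.

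Other splits of the libraries were counted for the numbers of calls. For each pair of groups, 1 of the 10 splits of 6 libraries, the real one, gave as many genes. The real counts were 412 at day 2, 5605 at day 4, 7177 at day 6, 4306 from day 2 to day 4 and 4389 from day 4 to day 6 in fits of the 2 groups alone, and the highest of the other splits gave 1 gene at day 2 and 0 in the rest. For gene lists, 4 of 10 splits gave as many calls at day 2 (14 in the real split, 18 in the highest other), 4 at day 4 (19 and 21) and 2 at day 6 (20 and 20), so splits that mix the groups called as many lists as the real ones. In each of these comparisons 10 splits are too few for a share under 0.05. Over the 4 groups, 100 splits were counted, with the real one put in by construction and the others drawn. Only the real one reached 8282 genes, and the highest other called 5546. Relabelling takes the libraries as independent, which technical replicates would not be, so this share is not read as excluding chance. For transient genes, 2 of 100 splits called at least 7, and the highest other called 4047. That split far exceeds the real count. Drawn splits mix days that differ in many genes, so no conclusion is drawn from it, and what it follows was not tested.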
